A study of Mus musculus with 6 samples.

How the data were processed

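RNA levels were measured in the dissected amygdala of 6 male 129S1/SvImJ mice aged 8 to 10 weeks, 3 on a zinc diet and 3 on a control diet, 2 h after fear extinction training. Each mouse gave 1 array. Per the labels' protocols, tissue was frozen, total RNA was purified with an on-column DNase step, and 500 ng of RNA was labelled with biotin by a 3′ in vitro transcription kit. It was hybridised to the Affymetrix Mouse430_2 array, a 1-colour array that reads the 3′ end of transcripts with probe sets. The labels name the diet "Zn" and "ZnR" without its zinc content, so whether it held more or less zinc than the control diet is not stated here, and it is called the zinc diet.

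The values used are the log2 probe set levels that the authors deposited as 1 table. R 2.15.1 and GCRMA 2.28.0 are named in the submitters' processing notes, without a role or order. GCRMA as usually run corrects background by probe sequence, normalises probes across arrays and summarises them per probe set; which of its options, filters or further steps were applied is not given in the sources used here. The log2 scale was read from the values, which the deposited table does not state; array medians lay between 4.04 and 4.09, and whether values were centred is unknown. The raw scanner files were not used here, so no detection call, background or saturation measure was at hand, and a low value cannot be told from background. GCRMA can compress or stretch differences near the low end of its range. Array-based precision is limited by the number of arrays, 3 per diet.

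The table held 45101 probe sets, of which 64 were control probe sets and were left out of the tests. The supplied platform annotation gave 1 gene symbol for 34958 probe sets and several for 932, and the remaining 9211 were unnamed here. Entrez numbers matched the RefSeq gene table of mouse assembly GRCm38.p6, used for names only, for 34754 of the single-symbol probe sets, and no symbol changed. No genome build applies to the values, so no coordinates are given. Probe sets were kept when their mean log2 level over all 6 arrays was at least 4, which left 22877 probe sets for 11221 named genes. No further normalisation was applied.

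Zinc diet and control diet were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, diet as the only term, all 6 arrays). P-values were adjusted with the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05, and the number past an unadjusted p of 0.01 was counted as well. Further alternatives were chosen after seeing the data: leaving Drd1 and Drd2 out of the striatal list, and leaving members outside the named group out of the lists taken by symbol prefix. Errors given as SE are the moderated standard errors of the log2 change unless another source is named, and SDs are over the 3 mice of a diet. In gene list tests, a gene was represented by its probe set with the highest mean over all arrays. The ribosomal and respiratory chain lists were taken by symbol prefix (Rpl and Rps; Nduf, Uqcr, Cox and Atp5). Lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists tested of 30 written. Camera with an estimated correlation and limma's fry were run as alternatives. Per-mouse quality measures and list means were compared with exact permutation tests, for which 3 mice against 3 cannot give a two-sided p under 0.1.

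The lists, the tests, the alternatives and the rule for the genes named were fixed before the data were examined, apart from those described as chosen later. The exact permutation tests of list means per mouse were not part of that plan. The rule took genes with 1 symbol whose 3 zinc diet values lay all above or all below the 3 control values. In each direction up to 12 past the adjusted threshold were to be named, filled up to 12 with the smallest unadjusted p. It added up to 4 genes of each list past its test and 11 genes named in advance, of which Ddx3y had no probe set with a single symbol and was not analysed here. List members given in the text outside this rule were chosen after their values were seen.

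The alternatives were no filter, a mean of at least 6, quantile normalization, median centring, eBayes with trend and robust settings, array weights, 1 probe set per gene, the mean of a gene's probe sets, the title number as a covariate, values under 4 set to 4, and leaving out each mouse. For the gene lists, median centring, trend and robust eBayes, array weights and values under 4 set to 4 were not run. Ranges of a list over all alternatives leave these out. The limma fit was tested on simulated data for 22877 probe sets with the measured means and residual spreads, independent between probe sets. With 3 mice per diet it recovered 68% of 100 probe sets changed by 1 log2 unit and 95% of 100 changed by 2 log2 units at the adjusted threshold, with 8 false calls. Of the unchanged probe sets, 1.24% had an unadjusted p under 0.01. Camera recovered a simulated list of raised genes and called 0 of the unchanged lists in that simulation. The simulated lists held independent probe sets, so this does not show how often camera with the preset correlation makes false calls in these data.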

Results

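Gene expression in the amygdala was profiled 2 h after fear extinction training in 3 mice fed a zinc diet (replicates 3, 7 and 10, as numbered in the labels) and 3 mice fed a control diet (replicates 1, 9 and 11). The mice were 129S1/SvImJ (S1), an inbred strain known for impaired fear extinction. The series as a whole concerns histone deacetylase inhibition, dopamine and the long-term inhibition of fear, and the single comparison in this data set asks how the diet affects amygdala transcripts after extinction. All 6 arrays had similar distributions, with a median log2 level of 4.08 ± 0.017 (SD, n = 3) in control mice and 4.07 ± 0.024 (SD, n = 3) in zinc diet mice. Pairwise correlations across the probe sets tested ranged from 0.991 to 0.996, and no 2 arrays were copies of each other.

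Transcripts known for their abundance in striatal medium spiny neurons and for their part in dopamine signalling were higher in the zinc diet mice. Scn4b, a sodium channel beta subunit, had a log2 level of 4.36 ± 0.54 (SD, n = 3) in control mice and 7.77 ± 0.53 (SD, n = 3) in zinc diet mice. The difference was 3.41 ± 0.34 (SE) or 10.6-fold, from a control level close to the filter of 4, so the size of the fold is uncertain. The orphan receptor gene Gpr6 was 5.11-fold higher (log2 change 2.35 ± 0.28 SE), and Rgs9, a regulator of G protein signalling, was 3.47-fold higher (1.80 ± 0.14 SE). The dopamine receptor genes Drd2 and Drd1 were 3.17-fold and 1.62-fold higher, with log2 changes of 1.66 ± 0.25 and 0.70 ± 0.13 (SE). Neither passed over all probe sets (limma adjusted p = 0.23 and 0.38). The control level of Drd2, 4.17 ± 0.51 (SD, n = 3), was also close to the filter of 4, so the size of its fold is uncertain. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, was 2.67-fold higher (1.42 ± 0.20 SE).

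The striatal medium spiny neuron and dopamine signalling list rose as a set, with 19 of its 20 tested genes higher and a median log2 change of 0.60 (camera adjusted p = 5.2e-24, preset correlation). The call was lost with an estimated correlation (adjusted p = 0.34 with an estimated correlation), while fry's directional test, which tests whether the genes move one way on balance, gave an adjusted p of 0.018. Over all alternatives its adjusted p ranged from 2.5e-29 to 0.34. In 16 of the 20 genes all 3 zinc diet mice lay above all 3 control mice. These 16 genes also passed when p-values were adjusted over the list alone, and 0 of the 20 passed over all probe sets tested. Rgs9, Gpr6, Drd1, Drd2 and Ppp1r1b were among them, whereas Scn4b is not in the list. The others included the transcription factor genes Isl1 (1.37 ± 0.18 SE), Foxp1 (0.84 ± 0.19) and Meis2 (0.47 ± 0.099), the cyclic nucleotide phosphodiesterase gene Pde10a (0.96 ± 0.18), Rasd2 (0.95 ± 0.12), and the neuropeptide precursor genes Penk (0.35) and Tac1 (0.35). Among marker lists of other cell types, the mean level per mouse separated the diets for endothelial and pericyte markers (7.111 to 7.172 in zinc diet mice, 6.974 to 7.107 in control mice), excitatory neuron markers (9.56 to 9.66 against 9.43 to 9.51) and the 4 hippocampal markers tested (6.25 to 6.39 against 6.12 to 6.22). Each had an exact permutation p of 0.1, the smallest this design allows. The endothelial and pericyte ranges nearly met. Of the 4 hippocampal markers, 2 were higher and 2 lower, with the largest change, 0.82, in Pou3f1. The diets overlapped for myelin markers (8.44 to 9.09 against 8.21 to 8.68) and choroid plexus markers (5.48 to 6.13 against 5.85 to 8.32).

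**Figure D1:**
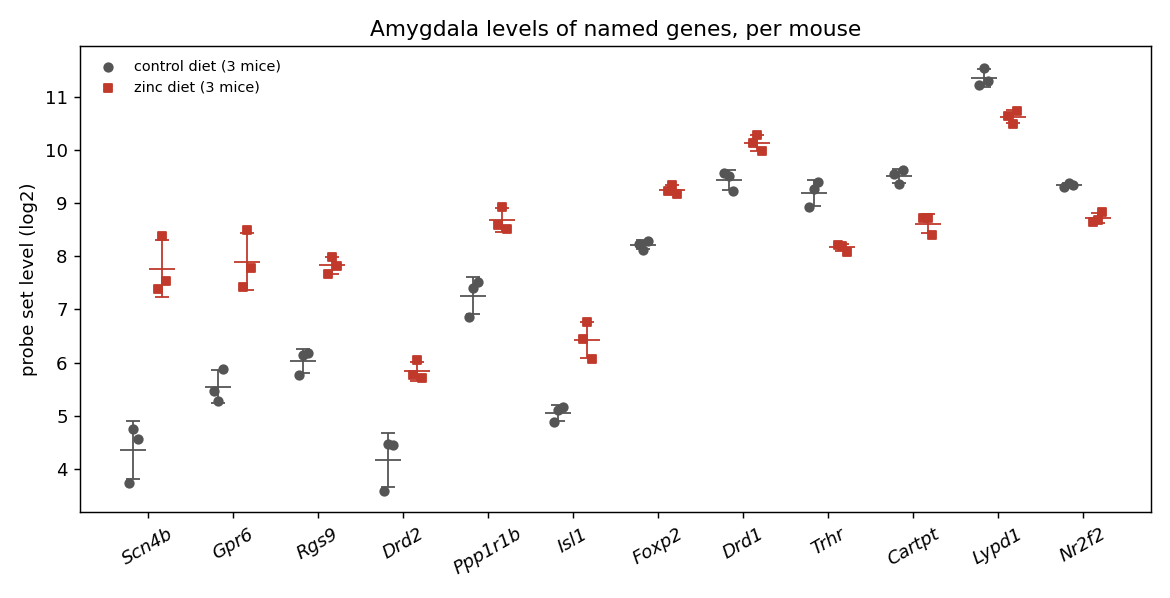
Log2 probe set levels (vertical axis) of 12 named genes (horizontal axis) in each of the 3 control diet mice (grey circles) and 3 zinc diet mice (red squares), with the mean and SD of each diet. The groups do not overlap for any of the 12 genes shown, which were chosen by separation or named in advance, and none passed the adjusted threshold over all probe sets.

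Among the other genes with the smallest p-values and higher levels, Foxp2, a forkhead transcription factor gene, was 2.05-fold higher at 9.25 ± 0.084 against 8.21 ± 0.084 (SD, n = 3 each), and its 3 other tested probe sets were higher too. Nt5e, which encodes the adenosine-producing ecto-5′-nucleotidase, had a log2 change of 0.94 ± 0.099 (SE). Inf2 (0.81 ± 0.094), Sertad4 (0.72 ± 0.083), Stbd1 (0.94 ± 0.13) and Ivns1abp (0.61 ± 0.069) completed this group together with Npnt (0.75 ± 0.10). The control levels of Stbd1 (4.31) and Npnt (4.06) were close to the filter of 4, so the size of their changes is uncertain. A second tested probe set of Npnt showed 0.01 ± 0.11, and the 2 other tested probe sets of Ivns1abp showed 0.24 and 0.25. Of the 12 higher genes named by the rule, 4 belonged to the striatal list. The probe sets of Rasd2, Npnt, Hopx, Meis2, Mt1, Hdac2, Rarres2, Ttr and Xist are of designs that can match related transcripts.

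Genes lower in the zinc diet mice included those of a hormone receptor, a neuropeptide precursor and 2 developmental transcription factors. Trhr, the thyrotropin-releasing hormone receptor gene, was 2.03-fold lower, at 8.17 ± 0.068 against 9.19 ± 0.24 (SD, n = 3 each). Cartpt, the precursor of the CART peptides, was 1.86-fold lower (log2 change -0.90 ± 0.12 SE). Nr2f2, an orphan nuclear receptor gene, was 1.54-fold lower (-0.62 ± 0.080), and its 3 other tested probe sets gave -0.34, -0.68 and -0.87. Lypd1 (-0.74 ± 0.11), the homeobox gene Dlx1 (-0.38 ± 0.069), the semaphorin receptor gene Nrp2 (-0.52 ± 0.096), Hopx (-0.63 ± 0.12), Mylk (-0.46 ± 0.086), Ttc28 (-0.46 ± 0.092) and Capsl (-0.66 ± 0.12) were also lower. In each of them all 3 zinc diet mice lay below every control mouse, which the naming rule required. For Slc12a9 (-0.54), the lysosomal potassium channel gene Tmem175 (-0.45) and Mylk, a second tested probe set differed less, by -0.095 ± 0.097, -0.066 ± 0.12 and -0.27 ± 0.14 (SE), with the diets overlapping. The diets also overlapped on 1 other tested probe set each of Lypd1 (-0.77 ± 0.28) and Nrp2 (-0.44 ± 0.23). The zinc diet levels of Capsl (4.14) and Slc12a9 (4.11) were close to the filter of 4, so the size of their changes is uncertain.

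Across all 22877 probe sets, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.076, shared by Rgs9 and Foxp2. At an unadjusted p under 0.05 there were 1460 probe sets, where chance gives 1144. At an unadjusted p under 0.01 there were 349, where chance gives 229, and 238 of the 349 were higher in zinc diet mice. In the simulation, 1.24% of unchanged probe sets fell under that p, so 229 may understate the number chance gives. The diets did not overlap in 12% of probe sets, where chance gives 10%. Without zinc diet replicate 7 the count at 0.01 was 176, and without control replicate 1 it was 558. Rgs9 passed the adjusted threshold in 5 of the alternatives (adjusted p from 0.019 to 0.43 over all of its alternatives), Foxp2 in 2 and Scn4b in 1.

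The dopamine synthesis, transport, breakdown and receptor list had 5 tested genes of 12 and rose as a set (camera adjusted p = 0.043, against an adjusted p = 0.38 with an estimated correlation). Drd1 and Drd2, which the striatal list also holds, were the only members to pass adjusted over the list alone, and 0 passed over all probe sets. The other 3 tested members did not pass: Maoa (0.060 ± 0.23 SE) and Maob (0.056 ± 0.097), which encode monoamine-degrading enzymes, and Ddc (-0.039 ± 0.097), which encodes the decarboxylase of dopamine synthesis. The median of 0.060 therefore lay below the mean of 0.49. The adjusted p was 0.14 without zinc diet replicate 3, 0.080 without control replicate 9 and 0.12 without control replicate 11, within a range of 5.2e-04 to 0.38 over all alternatives. The median was 0.20, 0.19, 0.17 and 0.12 without control replicate 1, zinc diet replicate 7, control replicate 9 and control replicate 11.

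The serotonin and noradrenaline list rose (8 of 20 genes tested, median log2 change 0.16, camera adjusted p = 0.025, against an adjusted p = 0.38 with an estimated correlation). Its 1 gene past the threshold adjusted over the list alone was Htr1b, the serotonin 1B receptor gene, at 0.52 ± 0.076 (SE), with 0 over all probe sets. Adra2c (0.34 ± 0.11), Htr5a (0.24 ± 0.079) and Htr4 (0.49 ± 0.21) were next, with Htr4 at 0.26 without control replicate 1. Without control replicate 9 the adjusted p of the list was 0.055, and with fry it was 0.084, within a range of 0.0086 to 0.38 over all alternatives. The median was 0.031 with no filter.

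Myelin and oligodendrocyte markers rose as a list (16 genes, median log2 change 0.36, camera adjusted p = 0.043, against an adjusted p = 0.73 with an estimated correlation), with 0 genes past the threshold over all probe sets or adjusted over the list alone. Ermn (0.55 ± 0.23 SE), Mal (0.44 ± 0.20), Mog (0.72 ± 0.36) and Cldn11 (0.48 ± 0.25) had the smallest p-values. Without zinc diet replicate 7 they were 0.34, 0.25, 0.35 and 0.25, and without control replicate 9 Mal and Cldn11 were both at 0.27. The call was also lost with fry (adjusted p = 0.59), with the title number as a covariate (adjusted p = 0.084), and without zinc diet replicate 7 (adjusted p = 0.64), control replicate 9 (0.28) or control replicate 1 (0.099), within a range of 2.5e-04 to 0.73. The median was 0.13 without zinc diet replicate 7 and 0.23 without control replicate 9. Mean levels of the list were 9.09 in zinc diet replicate 7 and 8.21 to 8.68 in the other 5 mice.

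Choroid plexus and ependymal markers fell as a list (6 genes tested of 15, median log2 change -0.71, camera adjusted p = 0.0060, against an adjusted p = 0.56 with an estimated correlation). All 6 genes were highest in control replicate 9, where Ttr, the transthyretin gene, reached 14.7 against 9.39 to 12.3 in the other 5 mice. Kcnj13 stood at 7.56 in that mouse and at 2.94 to 3.45 in the others, and it and Kl passed the filter only through that mouse. Rarres2 (-0.40 ± 0.080 SE) was the 1 member past the threshold adjusted over the list alone, with 0 over all probe sets, and its change stayed between -0.51 and -0.35 in all its alternatives. Without control replicate 9 the median of the list was -0.033 (adjusted p = 0.72), and fry gave an adjusted p of 0.56, within a range of 2.7e-06 to 0.72 over all alternatives. It was -1.15 and -1.10 without control replicates 1 and 11.

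**Figure D2:**
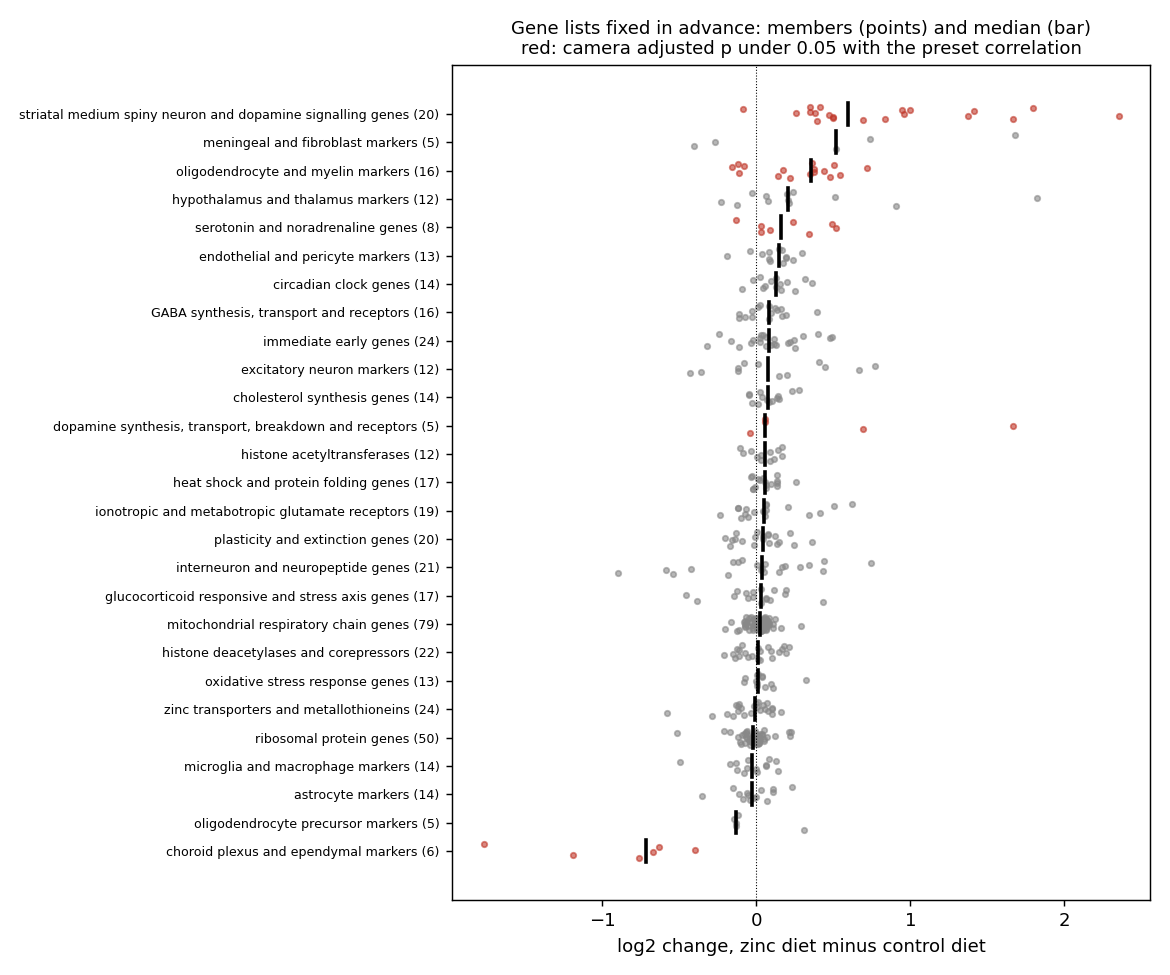
Log2 change (zinc diet minus control diet, horizontal axis) of every tested gene (points) of the 27 tested lists, with the number of genes in brackets and the median as a black bar. Red marks the 5 lists past an adjusted p of 0.05 in camera with the preset correlation; none passes with an estimated correlation. The ribosomal and respiratory chain lists, taken by symbol prefix, also hold kinase and assembly factor genes.

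Zinc-handling genes did not pass as a list (24 genes, median -0.0067, from -0.056 to 0.011 over the alternatives, camera adjusted p = 0.24), and 0 members passed over all probe sets or adjusted over the list alone. Slc30a3, the transporter that loads zinc into synaptic vesicles, was 8.00 ± 0.20 in zinc diet mice against 8.58 ± 0.31 in control mice (SD, n = 3; log2 change -0.58 ± 0.18 SE, limma adjusted p = 0.70). The metallothionein genes Mt2 and Mt1 gave -0.29 ± 0.098 (limma adjusted p = 0.73) and -0.15 ± 0.081 (limma adjusted p = 0.82). All 3 zinc diet mice lay below all 3 control mice for Slc30a3, Mt2 and Slc30a1 (-0.19 ± 0.082 SE), and above them for 2 other members. Histone deacetylases and corepressors gave a median of 0.011 over 22 genes (camera adjusted p = 0.70), which ranged from -0.026 to 0.025 over the alternatives (-0.0064 under quantile normalization) and in which camera's direction was down. Hdac2 differed by 0.10 ± 0.071 (SE, limma adjusted p = 0.86), and histone acetyltransferases gave a median of 0.060 over 12 genes (camera adjusted p = 0.50), from 0.0086 to 0.078 over the alternatives.

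Immediate early genes, the transcripts induced by neuronal activity, had a median of 0.080 over 24 genes and did not pass (camera adjusted p = 0.090), with 0 members past the threshold over all probe sets or adjusted over the list alone. Fos was 10.0 ± 0.77 in zinc diet mice and 10.1 ± 0.58 in control mice (SD, n = 3), a difference of -0.035 ± 0.43 (SE), and Bdnf differed by -0.11 ± 0.15 (SE) and, on its second tested probe set, by -0.27 ± 0.16. The list passed without control replicate 1 (adjusted p = 0.0030), without zinc diet replicate 7 (adjusted p = 0.0023), without zinc diet replicate 10 (adjusted p = 0.027) and with no filter (adjusted p = 0.024), within a range of 0.0023 to 0.87. Its median was 0.19 without control replicate 1 or without zinc diet replicate 7, 0.13 without zinc diet replicate 10, 0.039 without control replicate 9, 0.018 without control replicate 11 and -0.048 without zinc diet replicate 3. Nr4a2, an orphan nuclear receptor gene, had the smallest p of its members, with a log2 change of 0.40 ± 0.099 (SE).

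Neither the glutamate receptor list nor the GABA list passed. The glutamate receptor list had a median of 0.053 (19 genes, camera adjusted p = 0.35), in which Grm4 (0.50 ± 0.13 SE) and Grm8 (0.62 ± 0.18) were highest. Its median ranged from -0.027 (without control replicate 9) to 0.080 over the alternatives. The GABA list had a median of 0.083 (16 genes, adjusted p = 0.30; 0.022 without control replicate 9 to 0.11 without control replicate 1). Excitatory neuron markers had a median of 0.079 (12 genes, camera adjusted p = 0.56; 0.026 without control replicate 9 to 0.15 without control replicate 1) and moved both ways: Rspo2 (0.77 ± 0.17) and Neurod6 (0.67 ± 0.17) rose, while Lmo3 (-0.43 ± 0.11) and Neurod1 (-0.36 ± 0.10) fell when adjusted over the list alone, with 0 passing over all probe sets. In the interneuron and neuropeptide list (21 genes, median 0.038, camera adjusted p = 0.56), Cartpt was the 1 gene past the threshold adjusted over the list alone, with 0 over all probe sets. The mean of this list was -0.0035 and camera's direction was down, against the positive median, which ranged from -0.0046 to 0.061.

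The remaining lists did not pass with the preset correlation. Median log2 changes were 0.044 for plasticity and extinction genes (20 genes, adjusted p = 0.56), 0.031 for glucocorticoid and stress axis genes (17 genes, 0.95, with a mean of -0.0037 and camera's direction down), 0.13 for circadian clock genes (14 genes, 0.053), 0.15 for endothelial and pericyte markers (13 genes, 0.053) and -0.029 for astrocyte markers (14 genes, 0.56). They were -0.027 for microglia and macrophage markers (14 genes, 0.25), -0.13 for oligodendrocyte precursor markers (5 genes, 0.15), 0.52 for meningeal and fibroblast markers (5 genes, 0.23), and 0.20 for hypothalamus and thalamus markers (12 genes, 0.25). Heat shock genes gave 0.058 (17 genes, 0.30), oxidative stress genes 0.0082 (13 genes, 0.66), cholesterol synthesis genes 0.076 (14 genes, 0.25), genes with ribosomal protein prefixes -0.019 (50 genes, 0.25) and genes with respiratory chain and ATP synthase prefixes 0.024 (79 genes, 0.64). The prefixes also took in 7 genes outside the first group (6 S6 kinase family genes and Rps19bp1) and 8 Ndufaf assembly factor genes. Without them, as an alternative chosen after seeing the data, the medians were -0.016 (43 genes, adjusted p = 0.25) and 0.024 (71 genes, adjusted p = 0.60). Some of these lists passed under alternatives with the preset correlation. Endothelial and pericyte markers passed in 6, among them without control replicate 9 (adjusted p = 0.0085) and without zinc diet replicate 10 (0.022), within a range of 0.0061 to 0.41. Circadian clock genes passed in 4, among them without control replicate 1 (0.018) and without zinc diet replicate 7 (0.0079), within a range of 0.0079 to 0.56, and their median ranged from 0.051 to 0.18. Meningeal and fibroblast markers passed without control replicate 9 (median 0.72, adjusted p = 8.4e-05) and with no filter (median 0.22, adjusted p = 0.0063), within a range of 8.4e-05 to 0.79, and their median ranged from 0.22 to 0.72. Hypothalamus and thalamus markers passed without control replicate 1 (0.018) and without zinc diet replicate 10 (0.042), within a range of 0.018 to 0.93, and their median ranged from -0.059 to 0.30. Cholesterol synthesis genes passed without control replicate 1 (median 0.14, adjusted p = 0.015) and without zinc diet replicate 10 (0.12, adjusted p = 0.022), within a range of 0.015 to 0.87, and their median ranged from 0.034 to 0.14. Heat shock genes passed without zinc diet replicate 10 (median 0.097, adjusted p = 0.027), within a range of 0.027 to 0.87, and their median ranged from 0.016 to 0.097. The medians of the glucocorticoid (-0.020 to 0.067), astrocyte (-0.092 to 0.019) and microglia (-0.069 to 0.0023) lists turned sign among the alternatives. The hippocampus list kept 4 genes (median 0.070; Pou3f1, at 0.82 ± 0.20 SE, passed adjusted over the list alone), the interferon and inflammation list 3 (median -0.021) and the blood cell list 0, too few to test.

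Measures of RNA quality did not separate the diets. The 3′ minus 5′ difference of the Actb control probe sets was 0.83 ± 0.064 in zinc diet mice and 0.82 ± 0.10 in control mice (SD, n = 3, exact permutation p = 1), and that of Gapdh was -0.14 ± 0.038 against -0.088 ± 0.058 (SD, n = 3, exact permutation p = 0.3). The smallest p this design allows is 0.1. Control probe sets for 18S rRNA varied between mice, from 10.7 in control replicate 1 to 12.6 in control replicate 9 and zinc diet replicate 3. Xist, transcribed from the inactive X chromosome of female cells, lay below the filter at 3.24 ± 0.034 in zinc diet mice and 3.12 ± 0.13 in control mice (SD, n = 3), and the labels give all mice as male.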

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

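No paired analysis was possible because the groups share no replicate numbers. The count of 0 probe sets at an adjusted p of 0.05 became 2 (Rgs9 and Foxp2) with a mean of at least 6, 3 (also Scn4b) with trend and robust eBayes, and 1 (Rgs9) with 1 probe set per gene, with the mean of a gene's probe sets or with the title number as a covariate; it was 0 without each mouse. The count of 349 at an unadjusted p of 0.01 became 550 with no filter and 628 with array weights, and ranged from 176 (without zinc diet replicate 7) to 558 (without control replicate 1). The 5 lists called became 0 with an estimated correlation, 2 with fry (the striatal and dopamine lists) and 9 with no filter, and ranged from 3 (without control replicate 9) to 10 (without zinc diet replicate 10). The striatal list kept its direction in all alternatives run for lists, with medians of 0.50 to 0.72. Among these, which did not include array weights, it lost its call only with an estimated correlation. Leaving out Drd1 and Drd2, chosen after seeing the data, gave a median of 0.50. Of 776 recomputed values of 47 named genes, 760 kept sign and side and 8 turned sign: Fos (-0.48 to 0.30 without each mouse) to 0.30, 0.23 and 0.14 without control replicate 1 or zinc diet replicates 7 or 10, Bdnf (-0.20 to 0.031; -0.27 on its second probe set) to 0.031 without control replicate 9, Maob (-0.028 to 0.12) to -0.017 with array weights and -0.028 without control replicate 1, and Maoa (-0.19 to 0.20) to -0.054 and -0.19 without zinc diet replicate 3 or control replicate 11. The 12 higher and 12 lower genes turned sign in 0 cases. They were selected for complete separation of the diets, so leaving out a mouse could not turn their sign. A change of filter or of eBayes setting leaves a probe set's log2 change as it is. The sign was thus fixed in advance in part of the 760 as well. The difference in the share of probe sets at 4 or more, -0.088 percentage points, was 0.020 at 6 or more. Apart from fewer probe sets or mice, the cause was not tested. Without background measures, levels near 4 are the least certain.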

Other observations

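The tests of the central amygdala list, of the deviations of the striatal genes within diets, of the further choroid plexus markers as given here, of the choroid plexus list without control replicate 9, of the first principal component and of unnamed probe sets, and the counts of splits for probe sets, as well as the alternatives, per-mouse means and list tests of the further striatal markers, were chosen after the results they bear on were seen. Beyond the lists of the report, a further 25 striatal region markers, chosen outside the dopamine signalling genes, were written down before their values were seen, and 22 were tested. Slc35d3 among them is known to act in dopamine D1 receptor trafficking. Of these, 21 were higher in zinc diet mice and 12 had an unadjusted limma p under 0.05 with a higher level, with 0 lower at that p. Ido1 (log2 change 1.53 ± 0.27 SE), Sh3rf2 (1.30 ± 0.23), Nexn (0.96 ± 0.22), Strip2 (0.92 ± 0.19), Slc35d3 (0.91 ± 0.24) and the transcription factor gene Ebf1 (0.91 ± 0.22) were the highest, and Coch (-0.59 ± 0.27) was the 1 lower gene. Arpp21, the one with the highest level, stood at 13.0 in control mice and 13.1 in zinc diet mice, while the control means of Ido1 (3.49), Nexn (3.55), Gpr149 (3.75), Lrrc10b (3.77) and Sh3rf2 (3.87) lay under 4, so these 5 passed the filter through the zinc diet mice. Without these 5 the median log2 change was 0.18 over 17 genes instead of 0.31 over 22, without Slc35d3 it was 0.29, and without each mouse it ranged from 0.24 to 0.39. Tested beside the 27 lists, the 22 genes had a camera p of 0.042 with an estimated correlation (adjusted p = 0.32) and a fry p of 0.0095 (adjusted p = 0.066). Peptide genes of the neighbouring hypothalamus varied widely between mice within a diet, with SEs of 1.43 for Pmch (1.82) and 1.98 for Avp (0.91).

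The higher striatal genes in zinc diet mice may reflect how much striatal tissue, which borders the amygdala, the dissected pieces held. The median log2 change of the 22 further markers was 0.31, above 100% of 10000 random lists matched on expression (their central 95% ran from -0.044 to 0.067), a percentile that ignores the correlation between genes and the spread between the 3 mice of a diet. Per mouse, the mean of these markers was 7.99 to 8.24 in zinc diet mice and 7.51 to 7.71 in control mice. The difference was 0.46 ± 0.10 (SE from the pooled variance of the per-mouse means, exact permutation p = 0.1, the smallest possible here). It includes the 5 markers that passed the filter through the zinc diet mice, which can enlarge it, and it was not recomputed without them. Of the other 17 markers, 16 were higher, with a median of 0.18. Higher levels thus reached markers chosen outside dopamine signalling, as a larger striatal share would give. This goes against a change limited to dopamine signalling genes, but an exact permutation p of 0.1 cannot exclude one. A larger central amygdala share cannot be told apart from none: its 10 markers had a median of 0.014 and went both ways (most are also in the interneuron and neuropeptide list), with Cartpt at -0.90 and Crh at 0.43. Within diets the 20 striatal genes co-varied in part (mean correlation 0.32, against 0.12 at the 95th percentile of 1000 random lists), and a striatal gene programme raised by the diet stays open, since bulk tissue from 3 mice per diet cannot separate it from tissue composition.

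The call of the choroid plexus list ended without control replicate 9, although Rarres2 stayed lower in zinc diet mice, and a candidate explanation for the list is choroid plexus tissue in that piece. A filter over all 6 arrays let that mouse itself select markers, so the further markers were taken by their mean over the other 5 arrays. Of the 6 kept, 5 were highest in that mouse (Igf2 was 9.01 there and 7.25 to 7.77 elsewhere), and with no filter 13 of 15 were. Without that mouse the list's median was -0.033. The SE of that median, 0.21, came from the spread over the list's 6 genes and does not measure the spread between mice. A diet effect is not excluded and stays open.

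The first principal component (32.2% of the variance) followed the number in the sample title, with Spearman's rho of 1 (exact permutation p = 0.0028, n = 6; 0.0083 adjusted over 3 components) and Pearson's r of 0.96 (exact permutation p = 0.0014). Without the 2 mice farthest from the median number, r was 0.88. With diet in the model, 748 probe sets had an unadjusted limma p under 0.01 for the number, 1 (a Gnas probe set, with a slope of -0.25 per number) had an adjusted p under 0.05, and 599 of the 748 were lower at higher numbers. Probe sets without a single gene symbol made up 36.9% of those 599 against 14.1% of all tested, and 5 of the 7 probe sets of the nuclear RNA Malat1 were lower at higher numbers at an unadjusted limma p under 0.05, with 0 past an adjusted p of 0.05 and 1 without a trend (slope -0.0012); this is consistent with more nuclear or unspliced RNA at low numbers, as a hypothesis. The Actb 3′ minus 5′ difference was 0.90 and 0.94 in the mice numbered 10 and 11, against 0.75 to 0.79 in the others. That of Gapdh was highest (-0.044) in the mouse numbered 1 and lowest (-0.18) in that numbered 3. Whether these measures follow the number was not tested. What the numbers stand for is not given, and time of day stays open. The clock list gave a camera p of 0.12 for the number, and a p that misses the threshold does not exclude a change.

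Immediate early genes were lower at higher title numbers with diet in the model (camera adjusted p = 2.0e-10, against an adjusted p = 0.87 with an estimated correlation), as were cholesterol synthesis genes (1.8e-05, against 0.87) and hypothalamus and thalamus markers (0.0014, against 0.87).

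The 6 mice split into 3 and 3 in 10 ways, too few for a share under 0.05. The count at an adjusted p of 0.05 was 0 in all 10 splits. At an unadjusted p of 0.01, 3 of the 10 splits gave at least the real 349, and the highest other split gave 540. Gene lists past the threshold numbered at least the real 5 in 5 of the 10 splits, with 6 as the highest other. The striatal list itself passed in 5 of the 9 other splits, with a lowest adjusted p of 9.0e-05 against 5.2e-24 in the real split. Its mean difference was 0.83 in the real split and at most 0.40 in another, which follows from the separation of the diets already given. Every other split mixed the diets unequally, so part of any diet difference remained in it. These splits therefore do not give a rate of false calls for this list.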
